A study of Mus musculus with 3 samples.

How the data were processed

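CUT&Tag libraries were made from cells of the ganglionic eminences of wild-type mice at embryonic day 16.5. Per the design text of the series, a single pool of cells was divided into 3 parts, 2 with anti-FOXG1 antibody (FOXG1 replicates 1 and 2) and 1 without it (the no-antibody control). The FOXG1 replicates are therefore technical aliquots, and p-values measure nothing about variation between animals. Groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, cutadapt, Bowtie2, MACS2 and deepTools were used with mouse build mm10. Versions, settings, read filters and whether the control library was given to the peak caller are not given in the sources used here.

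The deposited files were MACS2-style narrowPeak lists, 1 per library, so peaks were called by library and not on pooled reads. The fold enrichment in the deposited lists is a linear ratio of the summit pileup to the caller's local background. The −log10 p-value and the −log10 q-value in the deposited lists are the caller's tests of the summit against that background. The score column in the deposited lists is a whole number, 10 times the −log10 p, and was not used further. The summit position in the deposited lists is an offset in bp from the peak's start. The lowest −log10 p was 5.04, 5.01 and 5.00 in FOXG1 replicate 1, FOXG1 replicate 2 and the control, so a p cutoff had been applied before deposit. A fold is the authors' value for that peak in that library. It was used to describe, rank or filter peaks and, with the p-value, to recover depth. All peaks lay on chromosomes 1 to 19, X and Y.

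The files give no read totals. Depth was recovered by searching for the whole number of fragments at the summit, and its background, that give both the deposited fold (with a pseudocount of 1) and the Poisson −log10 p within 0.001, a tolerance that grew in proportion for −log10 p above 100. A single whole number was found for 100% of replicate 1 peaks, 99.92% of replicate 2 peaks and 99.95% of control peaks. In peaks simulated with the same formulas, 100% were recovered, which checks the search but not the formulas. The simulated pileups were far below the highest recovered ones. The pileup ranged from 14 to 13220 fragments in replicate 1, from 11 to 9908 in replicate 2 and from 3 to 1195 in the control. The lowest background of a library stands for its genome-wide coverage. For the control it is an upper bound, so ratios of the FOXG1 libraries to it are lower bounds. Median peak widths were 443, 420 and 484 bp. A control peak on 3 or 4 fragments has wide counting error. Intervals are 95% Wilson intervals for shares and conditional exact intervals for odds ratios. They cover counting error only.

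Peaks were compared by an overlap of at least 1 bp, against 1000 random placements of the peaks on their own chromosomes with seed 1 (one-sided permutation test, smallest p 0.001; 200 placements for the alternatives). On simulated lists with 3000 shared peaks planted as identical intervals, 0 were missed, which was fixed in advance because identical intervals always overlap. There 3028 shared peaks were found where chance alone gave 48.6. This checks the counting only. Overlapping peaks of the 3 lists were merged into 29273 regions, and the fold of a merged region in a library is that of its highest peak. A FOXG1-only region has a peak in both FOXG1 lists and none in the control list.

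Genes came from a table of the RefSeq annotation of assembly GRCm38.p6, the assembly that mm10 names, restricted to 21887 protein-coding genes. This table gives the start and end of a gene but neither strand nor exons, and no genome sequence was used. The planned promoter class was therefore replaced by regions whose midpoint lay within 1 kb of either gene end, the planned exon and intron classes by gene bodies, and transcription start sites by gene ends. A region was assigned to the gene whose body, extended by 5 kb on both sides, held its midpoint (the nearest gene end deciding between several), otherwise to the nearest gene end within 100 kb. Of the FOXG1-only regions, 4466 were assigned and 936 were not. Whether a region is exonic, intronic or in a UTR was not analysed here, and neither was the planned forkhead motif test. Regions in repeats or known high-signal sequence were not removed.

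Location was tested with Fisher's exact test, two-sided, of FOXG1-only regions against regions with a control peak. The 11 gene lists were tested the same way against all other regions, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. All members of the lists were found in the gene table. With list members given 2 times the weight of other regions in simulated draws, the test reached an unadjusted p under 0.05 in 96.0% of 200 draws for the subpallial list, 91.0% for the pallial list and 90.5% for GABAergic function. With equal weight, it did so in 5.5%, 4.0% and 6.0%. Lists share some members, such as Foxp2 and Robo2.

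Genes and regions named in the text follow a rule fixed before the data were examined: the 15 FOXG1-only regions with the highest lower fold of the replicates, the 5 regions of all 3 libraries with the highest lowest fold, the 20 list members with a FOXG1-only region and the highest lower fold, 23 fixed genes whatever their values, and the 5 control-only regions with the highest fold. Members of each list with a FOXG1-only region are named in addition. Values given for Bcl11b, Lhx8, Drd1, Drd2, Satb2, Sox2 and Hey1, and those of the gene-end regions outside the lists, were chosen after values were seen.

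Alternatives fixed beforehand were a stricter overlap, summits within 250 bp, −log10 q or fold of at least 5, equal numbers of top peaks, other merging and control distances, other gene-end windows and assignments, genes as the unit, and each FOXG1 replicate left out. Alternatives added after seeing the data left out the control, peaks with −log10 p over 100 or regions with a background over 2 times the library's lowest in both replicates, or compared the lists with regions of a single FOXG1 replicate or among gene-end regions. A deep or wide peak may raise its own local background, so the background filter can also remove regions for their own signal. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.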

Results

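The genomic positions of FOXG1, a forkhead transcription factor of the developing telencephalon, were profiled by CUT&Tag in wild-type mouse ganglionic eminences at embryonic day E16.5. The ganglionic eminences are the ventral swellings of the embryonic telencephalon in which most GABAergic neurons of the forebrain are born. In CUT&Tag, a transposase tethered to antibodies bound on chromatin tags the DNA nearby, so that fragments accumulate where the antibody's target sits. The cells of a single pool were shared out among 3 libraries. Anti-FOXG1 antibody was added to 2 of them, and the remaining library, the no-antibody control, was taken through the assay without it. The title of the series places the experiment in a study of how pallial and subpallial GABAergic neurons are specified. The comparisons below ask where FOXG1 peaks were found in both antibody libraries, where the control also had a peak, and which genes lay nearby.

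The deposited data were 1 peak list for each library, in coordinates of mouse build mm10. FOXG1 replicate 1 held 8966 peaks covering 4.74 Mb, FOXG1 replicate 2 held 13841 peaks covering 6.92 Mb, and the control held 12416 peaks covering 6.15 Mb. The depth behind a peak was recovered from its deposited fold and p-value as the number of fragments stacked at the summit (the pileup). The median pileup was 23 fragments in FOXG1 replicate 1, 20 in replicate 2 and 6 in the control. In the control, 1874 peaks (15.1%) rested on 3 fragments. The lowest local background of any peak was 3.35 fragments in replicate 1, 2.22 in replicate 2 and 0.109 in the control, so that background coverage in the FOXG1 replicates was at least 30.7 and 20.4 times that of the control.

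The Foxg1 gene itself carried a peak in both FOXG1 libraries. This region, chr12:49383238-49384169, lay in the gene with its midpoint 0.821 kb from the nearer gene end, and its fold enrichment was 4.77 in replicate 1 and 5.43 in replicate 2. Regions found in both libraries also lay at Dlx1 and Dlx5, homeobox genes of subpallial GABAergic progenitors, at Foxp2, a forkhead gene of striatal neurons, and at Eomes, the T-box gene of cortical intermediate progenitors. Of the replicate 1 peaks, 5602 of 8966 overlapped a replicate 2 peak by at least 1 bp, or 62.5% (95% Wilson interval 61.5 to 63.5). Of the replicate 2 peaks, 5618 of 13841 overlapped a replicate 1 peak, or 40.6% (39.8 to 41.4). Random placement of the peaks on their chromosomes gave mean overlaps of 0.552% and 0.358%, and neither observed share was reached in 1000 placements (one-sided permutation p = 0.001 for both, the smallest possible). Because both libraries came from the same cells, this overlap measures technical repeatability, not variation between animals.

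Few of these positions had a control peak. Of the 5568 merged regions with a peak in both FOXG1 libraries, 5402 (97.0%) had none in the control and are called FOXG1-only regions here. They include the regions at Foxg1, Dlx1, Dlx5, Foxp2 and Eomes. Peaks of replicate 1 overlapped a control peak in 2.36% of cases (212 of 8966, interval 2.07 to 2.70) and peaks of replicate 2 in 1.74% (241 of 13841, interval 1.54 to 1.97). Replicate 1 peaks that replicate 2 shared did so in 2.86% (160 of 5602, interval 2.45 to 3.33). Small as they were, all 3 shares exceeded random placement, which gave 0.493%, 0.484% and 0.529% (one-sided permutation p = 0.001 each, the smallest possible).

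The pair of FOXG1 libraries shared far more regions than either shared with the control. Against the 5402 regions of both FOXG1 libraries without the control, 52 regions were common to replicate 1 and the control alone, and 78 to replicate 2 and the control alone. With the 8966 top peaks of each list by p-value, the numbers were 4618, 44 and 36. A comparison of 3 pairs allows no p below 0.33, so none was computed. The control was the shallowest library, and lack of a control peak there does not show lack of coverage: 47.5% of regions with a pileup of at least 300 in both FOXG1 libraries had a control peak, against 1.25% of those with at most 20. The number of FOXG1-only regions was 8754 when only replicate 1 was required, 13600 when only replicate 2 was required, and 2266 when every peak needed a fold of at least 5.

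**Figure D1:**
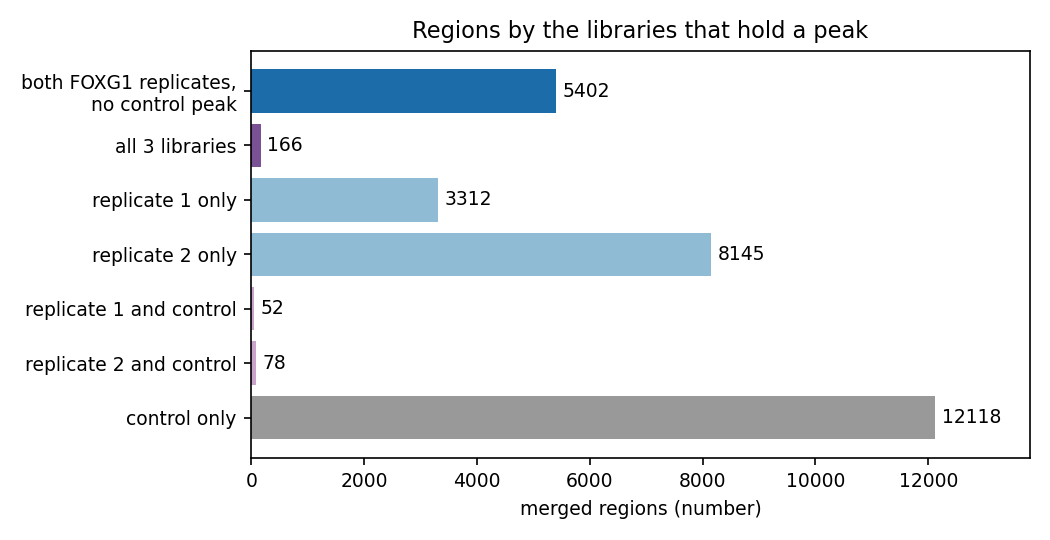
Number of merged regions (horizontal axis) for each combination of libraries that held a peak; each bar is a count without error. Both FOXG1 replicates without the control shared 5402 regions, while 52 and 78 regions were shared by a single FOXG1 replicate and the control.

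Among FOXG1-only regions, the highest enrichments belonged to narrow, very deep ones. The fold is a ratio to the local background, which a deep and wide peak may itself raise. This ranking may therefore in part reflect peak shape, which was not tested. First by the lower fold of the replicates was an Atrnl1 region (chr19:58113265-58113697, inside the gene), with a fold of 33.0 in replicate 1 and 37.5 in replicate 2 and pileups of 2483 and 1600 fragments. Regions assigned to Adgre5 (chr8:83756696-83757070; fold 32.4 and 37.1), Flt1 (chr5:147611435-147611711, inside the gene; 31.3 and 35.4) and Ttc21b (chr2:66189206-66189498, inside the gene; 29.6 and 36.0) followed. Flt1 encodes a VEGF receptor of blood vessels. The other regions among the top 15 of this class that could be assigned to a gene were those of Asmt, Lpp, Tcstv3, Wls, B230307C23Rik and Sos2, with a lower fold between 27.0 and 28.7. The remaining 5 had no protein-coding gene within 100 kb. All 15 had a −log10 p over 100 in both replicates, so their loss was fixed when such peaks were left out. None was kept either when regions with raised local background in both replicates were left out, which their own depth may explain. Both settings were chosen after seeing the data.

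Regions with a peak in all 3 libraries were also very deep at their top end. The 5 with the highest lowest fold were assigned to Rpusd4 (chr9:35305222-35305596; fold 29.8, 32.7 and 21.4 in replicate 1, replicate 2 and the control), Tmem196 (chr12:120028663-120029042; 26.8, 31.8 and 20.6) and Gm14496 (chr2:182012722-182013230; 23.6, 28.4 and 19.3), or had no gene within 100 kb (chrX:170880924-170881319 and chr14:124801556-124802244). The last of these was the deepest, with pileups of 12559, 9908 and 796 fragments. Among control-only regions the highest folds were 16.7 at chr15:60695958-60696476, with no gene within 100 kb, and 16.4, 15.5, 15.3 and 14.6 at regions assigned to Hsf2, Iffo1, Dhx40 and Btg1.

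Of 23 genes of forebrain patterning and GABAergic or glutamatergic identity fixed beforehand, 5 had a FOXG1-only region: Foxg1, Dlx1, Dlx5, Foxp2 and Eomes. Among all 21887 protein-coding genes, 3613 had one, so a count of 5 does not set these genes apart. The Dlx1 region (chr2:71528803-71529694) lay inside the gene, with a fold of 3.15 in replicate 1 and 3.87 in replicate 2. The Dlx5 region (chr6:6882074-6882587) had its midpoint 0.262 kb outside the gene, with a fold of 3.16 and 4.96. The Foxp2 region (chr6:14901327-14901846) lay inside the gene 0.238 kb from its nearer end, with a fold of 3.34 and 5.20. Eomes had 2 regions outside the gene, 76.7 kb (chr9:118401281-118401627; fold 4.75 and 5.96) and 35.6 kb (chr9:118442325-118442825; fold 4.37 and 5.97) from the nearest gene end. A separate control peak lay inside Eomes (chr9:118481428-118482054), with a fold of 8.57 on 11 fragments. Separate control peaks were also assigned to Foxg1, with 2, and Foxp2, with 1. These 6 regions rested on 19 to 34 fragments in replicate 1 and 19 to 40 in replicate 2. None of the 6 was kept at a fold of at least 5 in every peak, and those of Dlx1, Dlx5 and Foxp2 were not kept at a −log10 q of at least 5.

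The other fixed genes had no region common to both FOXG1 libraries without the control. In 11 of them, regions were found in a single FOXG1 library or at different places in the pair. Dlx2, Gad2, Nkx2-1, Lhx6, Sp8, Sp9 and Tbr1 had FOXG1 peaks in replicate 2 and none in replicate 1, with a fold of 4.58 at Dlx2 (chr2:71545799-71546464, inside the gene) and 4.42 at Gad2 (chr2:22621772-22622272, inside the gene). Gad2 also had a control peak elsewhere in the gene (chr2:22646295-22646741), with a fold of 6.97 on 8 fragments. Gad2 encodes a GABA-synthesising enzyme, and Nkx2-1 and Lhx6 specify neurons of the medial ganglionic eminence. Dlx6 and Neurog2 had FOXG1 peaks in replicate 1 and none in replicate 2, and Meis2 and Six3 had regions of each replicate at separate positions. Gad1, which encodes the other GABA-synthesising enzyme, and Emx1, a pallial homeobox gene, had a control peak and no FOXG1 peak, each with a pileup of 3 fragments and a fold of 3.61. No peak was assigned to Ascl1, Gsx2, Pax6, Emx2 or Neurod1 in any of the 3 lists, which at this depth does not show that FOXG1 was absent there.

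FOXG1-only regions lay close to gene ends far more often than regions with a control peak. Regions such as those of Hdac2 and Tle4, which encode co-repressor proteins, and of Ubc, Foxg1, Dlx5 and Foxp2 had their midpoints within 1 kb of an end of a protein-coding gene. This held for 1432 of the 5402 FOXG1-only regions (26.5%, interval 25.3 to 27.7) and for 585 of 12414 regions with a control peak (4.71%, interval 4.35 to 5.10). The odds ratio was 7.29 (95% interval 6.58 to 8.10; two-sided Fisher's exact test, −log10 p of 353.4). Random placement of the FOXG1-only regions put 3.06% near a gene end, with a highest value of 3.65% over 100 placements. The FOXG1-only regions near an end belonged to 1427 genes. Gene bodies held 48.6% of FOXG1-only regions and 43.7% of control regions, a small difference (odds ratio 1.21, interval 1.14 to 1.29; two-sided Fisher's exact test, p = 3.36e-09), against 40.2% for random placement. The direction turned among regions over 1 kb from a gene end, a comparison chosen after seeing the data. There gene bodies held 39.8% of FOXG1-only regions (1581 of 3970) and 42.9% of control regions (5070 of 11829; odds ratio 0.882, interval 0.819 to 0.95; two-sided Fisher's exact test, p = 0.000826). The gene-body excess of FOXG1-only regions thus came with those near gene ends. Regions are not replicates, so these p-values describe the 3 libraries. Background coverage in FOXG1 replicates 1 and 2 was at least 30.7 and 20.4 times that of the control. The contrast with control regions therefore cannot separate the antibody from depth. Placement at random was uniform along a chromosome, so the excess over it does not separate FOXG1 from other causes of fragments at gene ends.

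Among gene-end regions with −log10 p of at most 100, a group chosen after seeing the values, the highest lower folds belonged to Polr3k, Vmn2r29 and Elk3. Polr3k, which encodes an RNA polymerase III subunit, had a fold of 14.3 in replicate 1 and 13.4 in replicate 2 (chr2:181871088-181871498). The region assigned to Elk3, an ETS-family transcription factor gene, had 12.3 and 15.1 (chr10:93246786-93247263). Regions at Hdac2 (9.49 and 9.73), Lrrc42 (8.24 and 9.87) and Spop (7.19 and 11.9), which encodes a substrate adaptor of a ubiquitin ligase, were lower.

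The FOXG1 replicates differed in this respect. Regions found in replicate 2 alone, such as that of Dlx2, lay within 1 kb of a gene end in 36.6% of cases (2977 of 8145, interval 35.5 to 37.6), against 12.6% (416 of 3312, interval 11.5 to 13.7) of regions found in replicate 1 alone (odds ratio 4.01, interval 3.58 to 4.50; two-sided Fisher's exact test, p = 3.65e-159). The 166 regions of all 3 libraries had 10.8% near a gene end (18 of 166), and control-only regions 4.37% (4.02 to 4.74). Regions of replicate 2 and the control alone had the highest share, 44.9% (35 of 78, interval 34.3 to 55.9). Those of replicate 1 and the control alone had 5.77% (3 of 52, interval 1.98 to 15.6). The replicates thus differed also where the control had a peak.

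**Figure D2:**
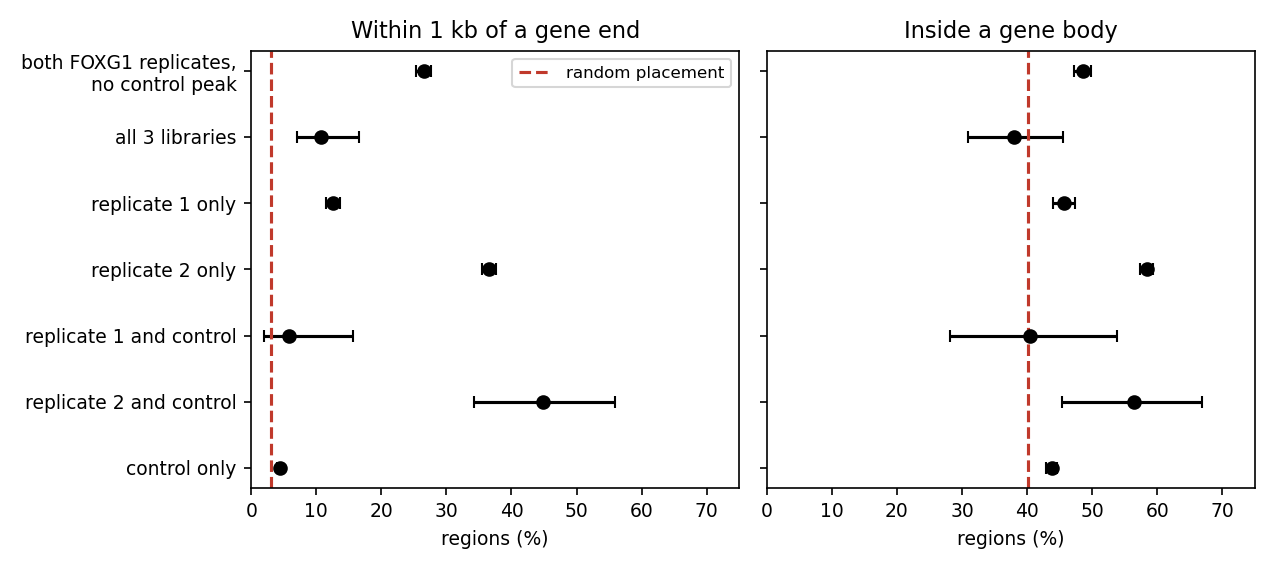
Percent of regions (horizontal axes) within 1 kb of an end of a protein-coding gene (left) and inside a gene body (right) for each combination of libraries; points are shares, bars are 95% Wilson intervals and the dashed line is the mean of random placements of the FOXG1-only regions. On the left, FOXG1-only regions sit at 26.5% and control-only regions at 4.37%, with random placement at 3.06%.

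FOXG1-only regions were assigned to 3613 protein-coding genes. They were then compared with all other regions over 11 gene lists fixed before the data were examined. No list passed the test: 0 of 11 had a Benjamini-Hochberg adjusted p under 0.05 (two-sided Fisher's exact tests over regions), and 3 lists, the subpallial GABAergic transcription factors, axon guidance and housekeeping, had an unadjusted p under 0.05. The odds ratio of every list but that of cell types from other organs lay on the other side of 1 under at least 1 alternative, so the directions given below are not firm.

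Transcription factors of subpallial GABAergic lineages had FOXG1-only regions at 10 of 38 members: Dlx1, Dlx5, Tshz1, Foxp2, Bcl11b, Lhx8, Sox6, Prox1, Zfhx3 and Rarb. A further 22 members had regions in a single FOXG1 library or at different places in the pair, but none shared. The highest lower fold in the list was that of Sox6, required for interneurons of the medial ganglionic eminence (chr7:115817900-115818856, inside the gene), at 9.43 in replicate 1 and 11.0 in replicate 2. Bcl11b, which encodes the striatal factor CTIP2, had 5.92 and 5.97, and Lhx8, a gene of cholinergic neuron specification, 5.55 and 5.91. These regions lay outside gene bodies, 30.2 kb (Bcl11b) and 92.6 kb (Lhx8) from the nearest gene end. Members held 12 FOXG1-only regions and 103 other regions, an odds ratio of 0.514 (interval 0.257 to 0.937; p = 0.0292, adjusted p = 0.13, Fisher's exact test). Random placement put 6 to 33 FOXG1-only regions at these genes (mean 20.7, 100 placements), a range that holds the observed 12. With genes as the unit the odds ratio was 0.99 (10 of 3613 genes with a FOXG1-only region, 23 of 8229 genes with other regions only; adjusted p = 1.0, Fisher's exact test), and at a −log10 q of at least 5 it was 0.276 and passed (adjusted p = 0.00671, Fisher's exact test). Without replicate 1 or replicate 2 it was 1.29 and 1.20 and did not pass, but there the comparison was with 12415 control regions, since regions of a single FOXG1 replicate no longer stood on the other side.

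Genes of GABAergic neuron function had FOXG1-only regions at 9 of 26 members: Slc6a1, Calb2, Reln, Drd1, Drd2, Tac1, Robo2, Nxph1 and Elfn1. Slc6a1, the GABA transporter GAT1, had a region 24.3 kb from the nearest gene end (chr6:114340974-114342588) with a fold of 10.9 and 12.3, in raised local background of 20.9 and 16.6 fragments. Tac1, the substance P precursor of direct-pathway striatal neurons, had a fold of 8.10 and 8.96 (chr6:7566568-7568065, 4.34 kb from the nearest gene end), also in raised background (9.62 and 6.03 fragments). The pileups there, 237 and 215 fragments at Slc6a1 and 85 and 62 at Tac1, may have raised this background themselves, which was not tested. The Slc6a1 region also lay in a dense 1 Mb window (114 to 115 Mb of chromosome 6) with 31 FOXG1-only regions, 30 of them at Hrh1 and Atg7. It lay outside the stretch that held those 30, and whether it shares their raised background was not tested. Reln had 7.50 and 8.43 (chr5:21908947-21909604, inside the gene) and Elfn1 6.67 and 9.90 (chr5:139982015-139982563). The dopamine receptor genes Drd1 and Drd2, of direct- and indirect-pathway neurons, had folds of 6.44 and 5.28 and of 4.14 and 7.45. The regions of Elfn1, Drd1 and Drd2 lay outside gene bodies, 7.56, 31.2 and 14.3 kb from the nearest gene end. The list held 12 FOXG1-only and 67 other regions (odds ratio 0.791, interval 0.389 to 1.48; adjusted p = 0.686, Fisher's exact test). The odds ratio was 1.37 with genes as the unit and 2.21 with assignment within 1 kb of a gene end only, neither past the threshold.

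Pallial glutamatergic transcription factors had FOXG1-only regions at 13 of 31 members: Lhx9, Neurod2, Eomes, Satb2, Cux1, Mef2c, Tcf4, Sox5, Bhlhe40, Pou3f2, Nfia, Nfib and Gli3. Sox5, a gene of deep-layer cortical neurons, had a fold of 7.49 and 9.91 (chr6:144594911-144595679, inside the gene), and Lhx9 6.21 and 7.90 (chr1:138788918-138789426, 36.0 kb from the nearest gene end). Satb2, a gene of callosal neurons, had 3.93 and 4.61 (chr1:56972757-56973120, inside the gene). The list held 20 FOXG1-only and 67 other regions, an odds ratio of 1.32 (interval 0.758 to 2.21; adjusted p = 0.592, Fisher's exact test). With assignment limited to regions within 1 kb of a gene end, 6 FOXG1-only and 4 other regions remained (odds ratio 6.63, adjusted p = 0.023, Fisher's exact test); set against gene-end regions alone, a comparison chosen after seeing the data, the odds ratio was 4.18 (adjusted p = 0.143). The direction turned, without passing the test, at a −log10 q of at least 5 (0.836) and without replicate 1 (0.936).

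Neural progenitor and Notch genes had FOXG1-only regions at 9 of 31 members: Sox1, Sox2, Sox9, Sox21, Hey1, Notch1, Vim, Ptprz1 and Ccnd2. The region at Sox2, a stem cell transcription factor gene, lay 0.63 kb from the gene end (chr3:34648874-34649855) with a fold of 4.50 and 4.49, and that at Hey1, a Notch effector gene, 0.09 kb from it (chr3:8666886-8667371) with 3.77 and 5.57. The list held 9 FOXG1-only and 45 other regions (odds ratio 0.884, interval 0.38 to 1.83; adjusted p = 0.861, Fisher's exact test). Limited to gene ends it also held 6 and 4 regions, with an odds ratio on the other side of 1 (6.63, adjusted p = 0.023, Fisher's exact test), and 4.18 among gene-end regions alone (adjusted p = 0.143). It was 1.37 with genes as the unit and 1.07 without replicate 1, neither past the threshold. Forkhead and co-repressor genes had FOXG1-only regions at 9 of 22 members: Foxg1, Foxp2, Foxo1, Foxo3, Foxn3, Foxj3, Tle1, Tle4 and Hdac2. Hdac2, a histone deacetylase gene, had a fold of 9.49 and 9.73 (chr10:36974030-36975104, 0.27 kb from the gene end), and Tle4, a Groucho-family co-repressor gene, 6.25 and 8.39 (chr19:14598133-14599140, 0.453 kb from it). This list held 10 FOXG1-only and 58 other regions (odds ratio 0.761, interval 0.347 to 1.5; adjusted p = 0.686, Fisher's exact test). Its odds ratio was 1.35 without replicate 1, 1.30 without replicate 2, 2.28 with genes as the unit and 2.95 within 1 kb of a gene end only, none past the threshold.

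Cortical hem and Cajal-Retzius genes had FOXG1-only regions at 5 of 23 members: Wnt5a, Bmp6, Lmx1a, Ebf3 and Zic1. Zic1 had a fold of 8.05 and 10.3 at 96.3 kb from the nearest gene end (chr9:91261381-91262184), Bmp6 7.70 and 8.49 at 7.28 kb (chr13:38338194-38338678) and Wnt5a 6.41 and 8.64 at 93.3 kb (chr14:28620296-28621113). The list held 5 FOXG1-only and 28 other regions (odds ratio 0.789, interval 0.238 to 2.07; adjusted p = 0.861, Fisher's exact test), and the odds ratio was 1.05 and 1.09 without replicate 1 or replicate 2 and 1.04 with genes as the unit. Axon guidance and migration genes had them at 8 of 27 members, Unc5c, Robo2, Slit3, Sema3c, Nrp2, Plxna2, Efna5 and Nrg3, with 10 FOXG1-only and 93 other regions (odds ratio 0.474, interval 0.22 to 0.912; p = 0.0213, adjusted p = 0.13, Fisher's exact test) against 20 to 49 regions on random placement (mean 33.6). With genes as the unit the direction of this list turned (1.14, adjusted p = 1.0, Fisher's exact test), as it did with assignment within 1 kb of a gene end only (1.26). Nrg3, a neuregulin gene, had a fold of 7.13 and 9.01 (chr14:38542252-38543203, inside the gene). Glial lineage genes had FOXG1-only regions at Sox10 and Mbp among 20 members, with 2 FOXG1-only and 16 other regions (odds ratio 0.552, interval 0.0616 to 2.35; adjusted p = 0.686, Fisher's exact test; 1.09 at a −log10 q of at least 5).

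Housekeeping genes had FOXG1-only regions at 7 of 20 members, Actb, Gapdh, Eef1a1, Pgk1, Ubc, Ywhaz and Polr2a, with 9 FOXG1-only and 16 other regions (odds ratio 2.49, interval 0.969 to 5.98; p = 0.0353, adjusted p = 0.13, Fisher's exact test). Random placement put 0 to 5 FOXG1-only regions at these genes (mean 1.13). The odds ratio was 1.03 at a −log10 q of at least 5, and 0.985, with 3 FOXG1-only regions left, without regions of raised local background, a setting chosen after seeing the data. Ubc, a polyubiquitin gene, had a fold of 7.11 and 7.52 (chr5:125386272-125387081, 0.712 kb from the gene end), in raised local background of 7.72 and 6.45 fragments. Markers of blood vessels, blood and microglia, cell types that dissected tissue can contain, had FOXG1-only regions at 4 of 30 members: Flt1, Sox17, Erg and Dcn (6 FOXG1-only and 19 other regions, odds ratio 1.40, interval 0.456 to 3.64; adjusted p = 0.686, Fisher's exact test). The odds ratio of these markers was 0.652 without replicate 1, 0.709 without replicate 2, 2.5 without the control, a setting chosen after seeing the data, and 0 within 1 kb of a gene end only, none past the threshold. Markers of cell types from other organs had none at any of 25 members, with 11 other regions (odds ratio 0, interval up to 1.76; adjusted p = 0.592, Fisher's exact test).

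**Figure D3:**
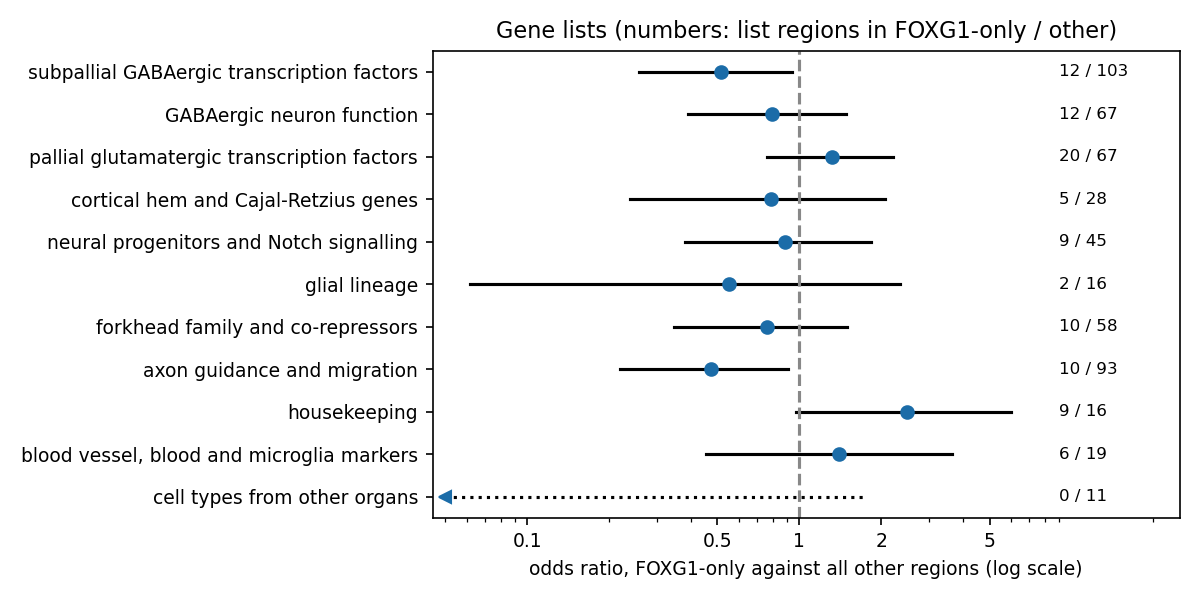
Odds ratio (horizontal log axis) for regions assigned to each gene list, FOXG1-only against all other regions; points are estimates, bars are 95% intervals, the arrow with a dotted bar marks an odds ratio of 0, and the numbers give FOXG1-only and other regions of the list. The estimates above 0 run from 0.474 for axon guidance to 2.49 for housekeeping, and 0 of 11 lists passed the adjusted test.

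**Figure D4:**
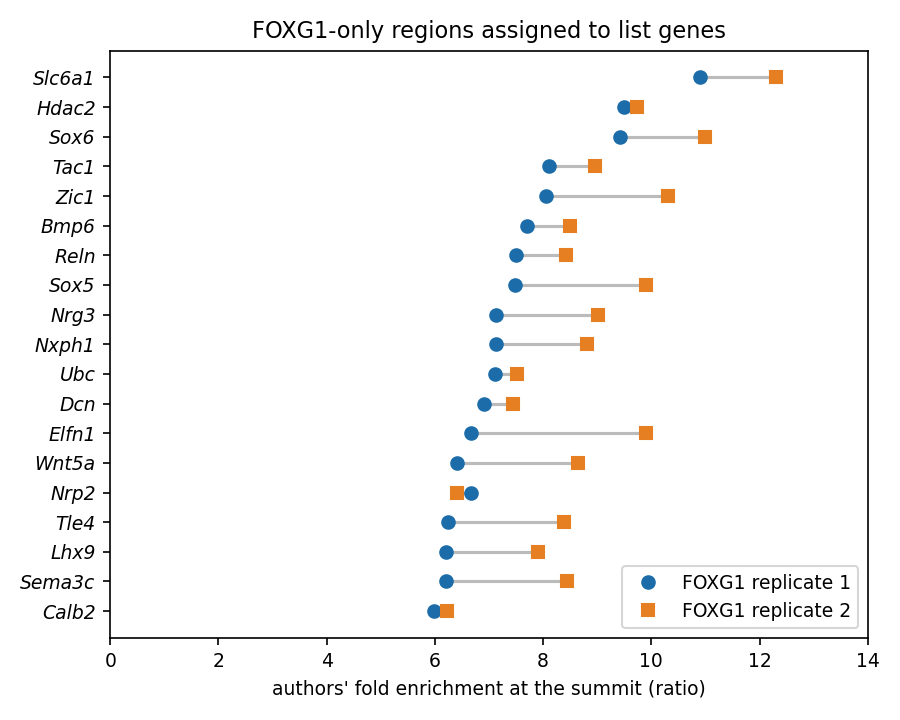
Fold enrichment at the summit, as the authors' peak lists give it (horizontal axis, ratio), for the list genes with the highest lower fold of the FOXG1 replicates; circles are replicate 1, squares are replicate 2 and grey lines join the values of a region. Flt1, at 31.3 and 35.4, is left off the axis; the values shown run from 5.98 for Calb2 to 12.3 for Slc6a1.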

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

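The alternatives that left out the control, very high peaks or raised background, and those that compared the lists with regions of a single FOXG1 replicate or among gene-end regions, and the gene-body comparison away from gene ends, were chosen after the results were seen. Both overlap results kept their direction and their side of the threshold under each alternative run, with 50.1 to 77.0% of replicate 1 peaks found in replicate 2, and 2.12 to 3.81% of peaks shared by the replicates with a control peak (1.74 to 2.36% of all peaks of the other replicate when a replicate was left out). The gene-end result did too, with odds ratios of 4.25 to 11.6 (5.44 to 9.72 without a replicate). The gene-body odds ratio was 1.11 to 1.52 where gene-end regions were included, but reversed to 0.882 among regions over 1 kb from a gene end. The number of FOXG1-only regions was 2266 at a fold of at least 5 and 8754 to 13600 without a replicate, by construction, since then fewer peaks or fewer libraries were required; under the other alternatives it was 4325 to 5569. Of the gene lists, 1 passed at a −log10 q of at least 5 (subpallial transcription factors, odds ratio 0.276, adjusted p = 0.00671, Fisher's exact test), 1 without the control library (the same list, 0.389, adjusted p = 0.0143) and 1 against regions of a single FOXG1 replicate (the same list, 0.396, adjusted p = 0.0206). With assignment within 1 kb of a gene end only, 2 passed (pallial transcription factors, odds ratio 6.63, and neural progenitors and Notch, reversed to 6.63, adjusted p = 0.023 each, by Fisher's exact test). Under the other settings 0 passed, also without either replicate; the adjusted p of the subpallial list ran from 0.00671 to 1.0 over its alternatives, and its odds ratio was 0.99 with genes as the unit. For gene ends part of the change is the choice of regions, since among gene-end regions alone both odds ratios were 4.18 (adjusted p = 0.143, Fisher's exact test); for the subpallial list the cause was not tested. A further 29 of 132 list values lay below the threshold on the other side of an odds ratio of 1. Of 40 named FOXG1-only regions, 24 were kept with −log10 p of at most 100, 22 without raised background, 34 at a fold of at least 5 and 37 at a −log10 q of at least 5. The forkhead motif test and its alternatives were not run, because no genome sequence was used, and taking every sequence in the files moved nothing. No paired analysis was possible because there was only 1 control library, so the groups share fewer than 2 replicate numbers. The control's depth limits every statement on lack of a control peak.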

Other observations

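The tests of control depth by pileup, of peak width, of the most distal regions and of raised coverage over the Hrh1 to Atg7 block were chosen after the results were seen; those of antibody dependence and of peak area in the block were written before. The genes named in this part were chosen after their values were seen. Of the 3613 genes with a FOXG1-only region, 3018 had 1 and 24 had 5 or more. Most regions were assigned to Hrh1, a histamine receptor gene, with 16, and to its neighbour Atg7, an autophagy gene, with 14. Sfi1 had 13, the predicted genes Gm40363, Gm15319 and Gm52481 had 12, 10 and 10, and Mid1 had 8. Apba2, Dlg2 and Scaf8 had 6 each. Dlg2 encodes a postsynaptic scaffold protein. Those with 5 included Arid1b, Fam155a, Maml3, Pls3, Ptprn2, Tmem267 and Vmn1r2.

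A small part of the FOXG1-only regions was gathered in dense windows. Of 2097 windows of 1 Mb with such a region, 23 held 10 or more, and together these held 343 of the 5402 regions; the median over windows was 2. The densest lay at 20 to 21 Mb of chromosome 8 with 34 regions, at 114 to 115 Mb of chromosome 6 (Hrh1, Atg7 and the Slc6a1 region) with 31 and at 85 to 86 Mb of chromosome 1 with 22. The median number of control peaks was 7 in the dense windows and 5 in the others. Of the 38 subpallial transcription factors, 11, Dlx2 among them, had FOXG1 peaks in replicate 2 only, 4 in replicate 1 only and 7 in both but at different places.

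Nearly all regions of both FOXG1 libraries, those of Foxg1, Dlx1 and Dlx5 among them, lacked a control peak. The control's shallowness is a candidate explanation: with a pileup of at least 300 in both replicates, 47.5% of regions (38 of 80, interval 36.9 to 58.3) had a control peak, against 1.25% (28 of 2236) at 20 or fewer (two-sided Fisher's exact test, p = 1.95e-42). Signal that depends on the antibody cannot be told apart from it for most regions. At least 94.3% of the 5568 regions were too low to give 3 fragments in the control at equal relative coverage. At most 316 were deep enough, since the depth ratios used are lower bounds. Of these 316, 65 (20.6%) had a control peak. Most thus lacked one, which the prediction written before for antibody-dependent signal required. This does not decide the question, because some of the 316 may be too low at the true depth ratio. Few control fragments and narrow regions may also leave peaks uncalled. With a pileup of at least 300, regions up to 400 bp wide, measured on FOXG1 peaks merged without the control, had a control peak in 15.0% of cases (3 of 20) and wider ones in 58.3% (35 of 60; two-sided Fisher's exact test, p = 0.000785), so a minimum peak length of the caller may hide control signal at narrow, deep regions such as that of Flt1.

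The most distal region of both FOXG1 libraries on 12 of 21 chromosomes had a pileup of at least 300, a level that 1.44% of all such regions reached, with medians of 3717.5 and 2942.5 fragments in replicates 1 and 2. Those assigned to Tmem196, Gm14496, Tcstv3, Wls and B230307C23Rik are among them. A control peak was present at 58.3% (7 of 12), against 159 of the 5556 other regions (two-sided Fisher's exact test, p = 1.29e-08), as it would be if this sequence were covered whether or not the antibody was present. Other regions with a pileup of at least 300 had a control peak in 31 of 68 cases, and no difference from them was detected (p = 0.535, Fisher's exact test). At each of the 7 with a control peak, the FOXG1 pileups were under 30.7 (replicate 1) and 20.4 (replicate 2) times the control pileup. These factors are lower bounds of the depth ratios. Closest to them was chr10:130594405-130595043, with 2242, 1628 and 90 fragments. The control thus covered these 7 at least as strongly for its depth, which argues against added antibody signal there. The rest had no control peak to compare. Reads from repeats near chromosome ends could give such depth, and this and FOXG1 binding at the rest were not tested.

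The 30 FOXG1-only regions at Hrh1 and Atg7 lay in a block of 133 kb (chr6:114496773-114629650). Its local background was 7.9 times the lowest of the library in replicate 1 (range over peaks 5.01 to 12.7) and 9.57 times in replicate 2, against 1.18 and 1.27 for the median of all peaks, so coverage may be raised over the whole block. The called peaks themselves made up at most 0.683 and 0.718 of that background (median over peaks), since each was counted at its summit height over its whole width. Even so counted, they did not reach the whole of it at the median peak. These values lay between the bounds set beforehand, and the true shares may be lower. Peaks raising their own background therefore cannot be told apart from broad coverage. The control had 1 peak there, where an even spread gives 0.62, which is too few to test whether the control shares the block. Extra copies of this stretch in the mice used, or a broad domain of FOXG1, stay open and were not tested.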
